A study of Mus musculus with 8 samples.

How the data were processed

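The samples were mouse fetal liver cells taken on embryonic day E14.5 from crosses of a Flt3-Cre strain with the mTmG reporter strain. In this reporter, every cell makes the red protein Tomato until Cre recombination switches it for good to the green protein GFP, so GFP marks cells with a history of Flt3-Cre activity. Per the labels, cells negative for lineage markers and positive for Kit, Sca1 and CD150 were sorted by flow cytometry into a Tomato+ and a GFP+ fraction, with 4 libraries of each, 8 in all. Total RNA was extracted with Trizol and libraries were made with the NEBNext Ultra kit, per the labels. The labels number the libraries of each fraction from 1 to 4 but do not say whether these came from separate embryos, litters or sorting days. The authors' p-values can then reflect at most the spread between these libraries, which may be technical. How that spread entered them is not given in the sources used here.

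The values analysed were the authors' own comparison of both fractions, 1 table of 14268 rows. Per the submitters' processing notes, the tools used were Bowtie2 2.2.1, TopHat2 2.0.11, TopHat, bedtools and DESeq, with genome build mm9. The notes give no role for each tool, and the settings are not given in the sources used here. Per the file headers, the authors gave the mean signal of each row over all libraries and over each fraction as a baseMean, which is a normalized count averaged over libraries. The authors also deposited a fold change (the ratio of the group means), its log2 value, a p-value and an adjusted p-value. Checked on the rows, the overall mean equalled the average of both group means within a relative 4.0e-07, and the ratio equalled the Tomato+ mean over the GFP+ mean within 7.8e-07. No group mean was 0, so each ratio was finite and no pseudocount was used. The authors' adjusted p-value equalled the Benjamini-Hochberg adjustment of their p-values over all 14268 rows within 5.3e-08. A second header line stood after the first 1374 rows, which are the rows with an adjusted p under 0.1. It was dropped.

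The sign was turned throughout, so that a positive log2 value means higher in GFP+. The table used here holds no value for a single library. No test across libraries was therefore run, the depth of each library is unknown, and no SD, standard error or split of the libraries is given. The overall means ran from 2.47 to 59404, with a median of 214. The group means summed to 7926897 in GFP+ and 7111170 in Tomato+, and the 20 rows with the highest overall mean held 6.73% of the GFP+ sum and 5.19% of the Tomato+ sum. The table pairs each row's cluster identifier with a symbol. The 14268 rows carry 14033 different symbols, and 235 rows repeat a symbol of another row. No coordinates are given in the table, and the mouse reference at hand is of another build than mm9, so no positions are reported. How reads shared by near-identical genes were counted is not given in the sources used here, so values for globin, histone, ribosomal protein and Gapdh genes are uncertain.

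The main result was the number of rows with the authors' adjusted p under 0.05, with no fold threshold. Before the data were examined, 28 gene lists, the rule for named genes and a set of alternatives were fixed. The fixed plan was a test on values per library, or, where only the authors' comparison was at hand, a reading of that comparison. The latter applied. Of 597 listed genes, 532 matched a row, 6 of them through an older symbol in the RefSeq gene table. A gene with several rows was read from the row with the highest mean. For each list, the members past the authors' adjusted p of 0.05 were counted, and the count was repeated with the authors' p-values adjusted over the list alone. The list's median log2 value was set against the medians of 10000 random lists of the same size matched on mean expression in 20 bins, and the central 95% of those medians is given as a description of these libraries, not as a test. The share of called genes that were higher in GFP+ has an exact binomial interval, which takes genes as independent and is also a description.

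Genes were named by a rule with 3 parts. It took all sort and related surface genes of the first list, then the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 50 and a named symbol, then the 2 members of each other list with the smallest p-value. It named 67 genes, some of which are not reported here. Any other gene in the text was chosen after its values were seen, and is introduced as such. The alternatives that could be run were adjusted p thresholds of 0.1 and 0.01, a minimum change of 1 on the log2 scale, a minimum mean of 10 or 50, a recomputed and a Bonferroni adjustment, 1 row per symbol, random lists without matching, and centring on the median of rows with a mean of at least 50. Further marker lists for the closing section were written after the fixed lists had been seen.

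The list step was tested on simulated values for 14033 genes with the means of the GFP+ against Tomato+ comparison. The calls themselves are the authors' and could not be tested in this way. Of 200 random lists of 20 genes with no added shift, 5.5% lay outside the central range. These lists were drawn at random from the same genes as the lists they were set against, so a share of about this size follows from the design. Genes were simulated as independent, so the step was not tested for lists whose genes vary together. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.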

Results

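RNA was measured in E14.5 mouse fetal liver cells that carried the surface profile of hematopoietic stem cells and had either undergone Flt3-Cre recombination (GFP+, 4 libraries) or not (Tomato+, 4 libraries). The comparison asks how the 2 fractions differ in expression, in a study of a stem cell of development and its innate-like lymphoid progeny. The authors' group means and p-values are used, since the table holds no values per library.

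Most lymphoid-primed and B lymphoid genes had higher and most stem cell and platelet genes lower normalized counts in GFP+ than in Tomato+ cells. In the authors' deposited table, Ccr9, a chemokine receptor of lymphoid progenitors, had a mean of 437 normalized counts in GFP+ and 47.5 in Tomato+, a 9.19-fold difference. Vwf, the von Willebrand factor of platelets and endothelium, had means of 75.7 and 513 in the authors' deposited table, 6.78-fold lower in GFP+. Most measured hepatoblast, macrophage and erythroid genes were also higher in GFP+.

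At the authors' adjusted p under 0.05, 1069 of 14268 rows differed, of which 693 were higher and 376 lower in GFP+. The higher genes made up 64.8% of the calls (exact 95% binomial interval 61.9% to 67.7%). At least 2-fold differences were seen for 275 of the higher and 217 of the lower genes, and the median log2 change was 0.79 for the higher genes and -1.11 for the lower genes. Highly expressed genes leaned towards GFP+. Among 163 rows with a mean of at least 5000 the median log2 was 0.38, with 113 called higher and 0 called lower, against a median of 0.03 among rows with a mean from 50 to 5000. The count of calls was 699 at an adjusted p under 0.01, 492 with a minimum change of 1 on the log2 scale and 308 with a Bonferroni adjustment.

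**Figure D1:**
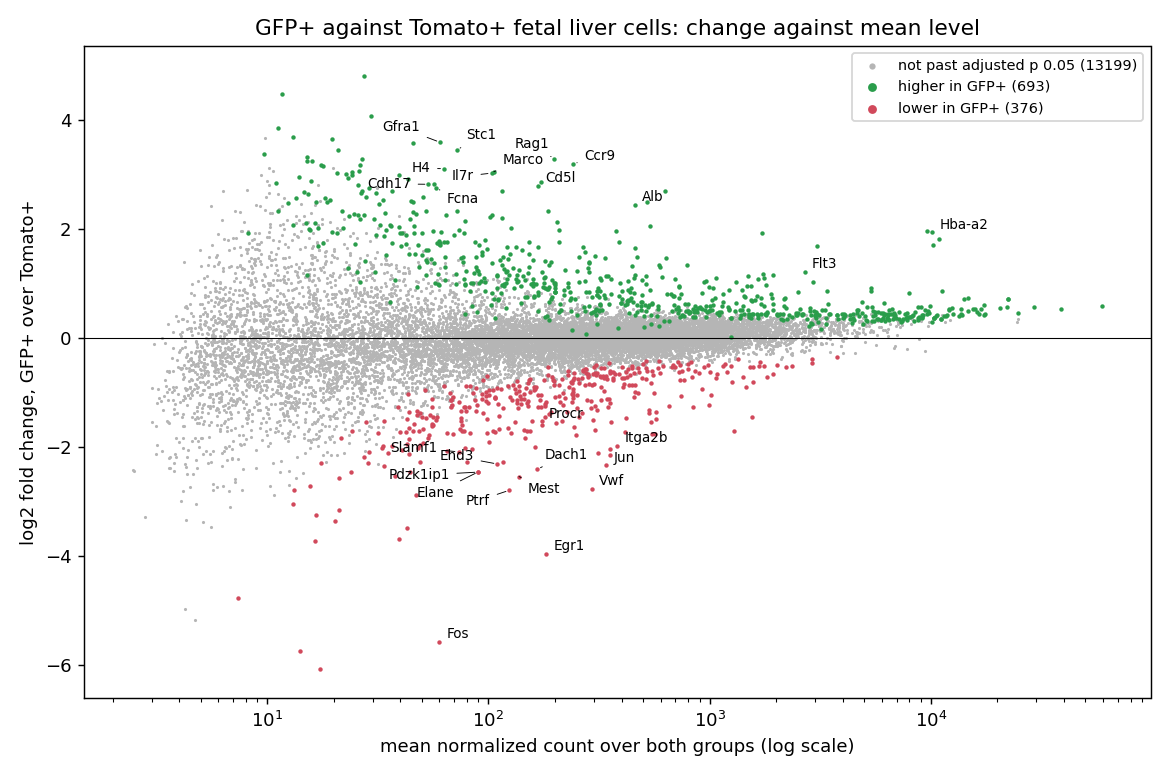
Each point is 1 row of the authors' deposited table, with its mean normalized count over both groups on a log scale on the x axis and its log2 fold change, GFP+ over Tomato+, on the y axis; green points are the 693 rows higher and red points the 376 rows lower in GFP+ at the authors' adjusted p under 0.05. Ccr9, Rag1 and Il7r stand among the largest rises, Fos, Egr1 and Vwf among the largest falls, and the rows with the highest means lie mostly above 0.

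Among the sort and related surface genes, 2 of 11 measured rose and 5 fell, and 2 rose and 7 fell with the p-values adjusted over the list alone. Flt3, the cytokine receptor whose Cre driver defines the fractions, had means of 3753 in GFP+ and 1617 in Tomato+, 2.32-fold higher in GFP+ (adjusted p = 2.03e-19, the authors' deposited table). Cd34 rose 1.58-fold in the authors' deposited table. Slamf1, which encodes the CD150 used in the sort, fell from 119 in Tomato+ to 27.9 in GFP+, 4.24-fold (adjusted p = 4.95e-08, the authors' deposited table). The stem cell surface genes Tek and Procr were 3.21-fold and 2.88-fold lower in GFP+ and Cd9 1.48-fold, per the authors' deposited table. Kit, Ly6a (Sca1), Cd48 and Thy1 did not pass, with log2 values of -0.28, -0.24, 0.32 and -1.68 in the authors' deposited table.

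Of 30 measured genes of stem cell identity, 21 fell and 0 rose, and with adjustment over the list alone 22 fell and 1 rose. The list's median log2 was -0.79, against -0.05 to 0.15 for the central 95% of matched random lists. Esam, an adhesion molecule of stem cells and endothelium, fell 4.33-fold in the authors' deposited table, from 511 to 118. Chosen after their values were seen, the transcription factor genes Mecom, Gata2 and Hlf were 2.90-fold, 2.06-fold and 1.30-fold lower in GFP+ in the authors' deposited table. The list shares 15 genes with other lists. Among Hox and Hox cofactor genes, 3 of 19 fell and 0 rose (4 fell and 1 rose adjusted over the list alone), with a median log2 of -0.63. Hoxb3 fell 3.28-fold in the authors' deposited table.

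Megakaryocyte and platelet genes were lower in GFP+. Of 23 measured, 15 fell and 0 rose (17 and 0 adjusted over the list alone), with a median log2 of -1.20 against -0.17 to 0.15 in matched random lists. Itga2b, the platelet integrin CD41, had means of 155 in GFP+ and 609 in Tomato+ in the authors' deposited table, and Pf4, chosen after its values were seen, had 96.9 and 265. Endothelial genes moved the same way, with 10 of 20 lower and 1 higher (13 and 1 adjusted over the list alone) and a median log2 of -0.91. Tie1, an endothelial receptor kinase, fell 2.35-fold in the authors' deposited table. Of 11 stellate and mesenchymal genes 3 fell and 0 rose, and 3 fell and 3 rose adjusted over the list alone, with a median of -0.87 that was -0.07 among members with a mean of at least 50. The basement membrane collagens Col4a1 and Col4a2 fell 3.40-fold and 3.38-fold in the authors' deposited table.

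Genes of multipotent and lymphoid-primed progenitors were higher in GFP+. Of 22 measured, 14 rose and 0 fell (14 and 1 adjusted over the list alone), with a median log2 of 0.57 against -0.05 to 0.20 in matched random lists. Rag1, a recombinase of antigen receptor genes, had means of 359 in GFP+ and 36.6 in Tomato+, and Il7r, the interleukin-7 receptor, 184 and 22.6, in the authors' deposited table. Notch1 rose 1.97-fold in the authors' deposited table (adjusted p = 1.89e-11). Of 19 B lymphoid genes 10 rose and 0 fell (14 and 0 adjusted over the list alone), and the median log2 was 2.76. Among members with a mean of at least 50 that median was 0.42. Igll1, Pou2af1, Cd79a and Ebf1, chosen after their values were seen, rose 28.2-fold, 16.9-fold, 8.01-fold and 8.30-fold in the authors' deposited table, from low Tomato+ means of 1.88, 3.28, 8.72 and 5.22. Pax5, the regulator of B cell commitment, also chosen after its values were seen, did not pass, with a log2 of 3.66 and adjusted p = 0.0504 in the authors' deposited table.

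Of 11 measured T and innate-like lymphoid genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone), with a median log2 of 0.92 against -0.43 to 0.24 in matched random lists. The list went both ways, with 6 genes above and 5 below 0 and a mean log2 of 0.39. Sox13, a transcription factor of gamma delta T cells, rose 1.90-fold and Tcf7, a transcription factor of early T cells, 3.30-fold in the authors' deposited table. The macrophage, hepatoblast and erythroid lists had medians in the same direction as these lymphoid groups, at log2 values of 2.13, 2.39 and 0.35, with 8 of the 24 erythroid genes below 0.

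**Figure D2:**
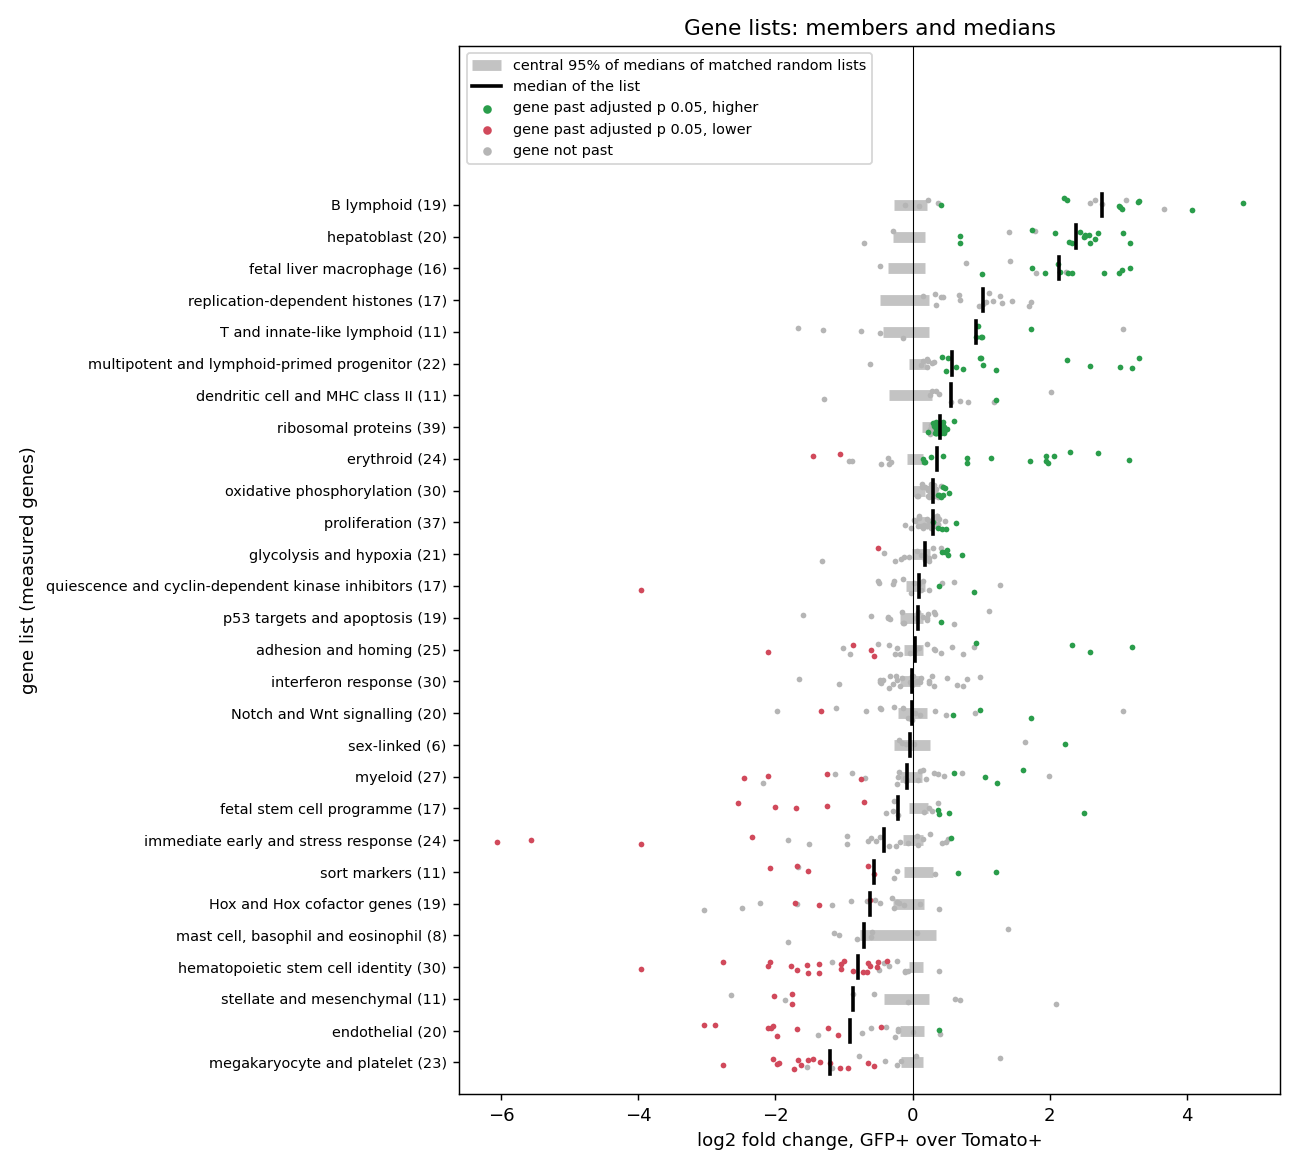
Each row is 1 of the 28 gene lists, with its number of measured genes in brackets and the log2 fold change, GFP+ over Tomato+, on the x axis; points are genes (green or red past the authors' adjusted p of 0.05, grey not past), black bars are list medians and grey bands the central 95% of medians of matched random lists. The medians of 19 lists lie outside their band, 11 above it and 8 below it.

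Genes of other fetal liver cells differed strongly. Of 20 hepatoblast genes 16 rose and 0 fell (16 and 1 adjusted over the list alone), with a median log2 of 2.39 that was 1.51 among members with a mean of at least 50. Alb, which encodes albumin, had means of 774 in GFP+ and 142 in Tomato+ in the authors' deposited table, and Afp, the alpha-fetoprotein of fetal hepatocytes, 885 and 157. Of 16 macrophage genes 11 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 2.13. Cd5l and Marco, both made by tissue macrophages, rose 6.93-fold and 8.31-fold in the authors' deposited table.

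Of 24 erythroid genes, 16 rose and 2 fell (16 and 3 adjusted over the list alone), with a median log2 of 0.35 against -0.09 to 0.16 in matched random lists. The rises include Blvrb and Rhag, chosen after their values were seen, with log2 values of only 0.18 and 0.15 in the authors' deposited table and p-values smaller than counting error alone would give, and Rhag had -0.0085 when both groups were scaled to the same total. The adult globin genes Hba-a2 and Hbb-b1 were 3.85-fold and 3.26-fold higher in GFP+ in the authors' deposited table, with Hba-a2 at 16122 and 4190 normalized counts. Chosen after their values were seen, Alas2, of heme synthesis, and Slc4a1, a red cell membrane protein, rose 4.19-fold and 3.83-fold in the authors' deposited table. The erythroid and megakaryocyte regulator Gata1, chosen likewise, fell 2.09-fold, and Klf1 and Epor did not pass, with log2 values of -0.46 and -0.89 in the authors' deposited table.

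**Figure D3:**
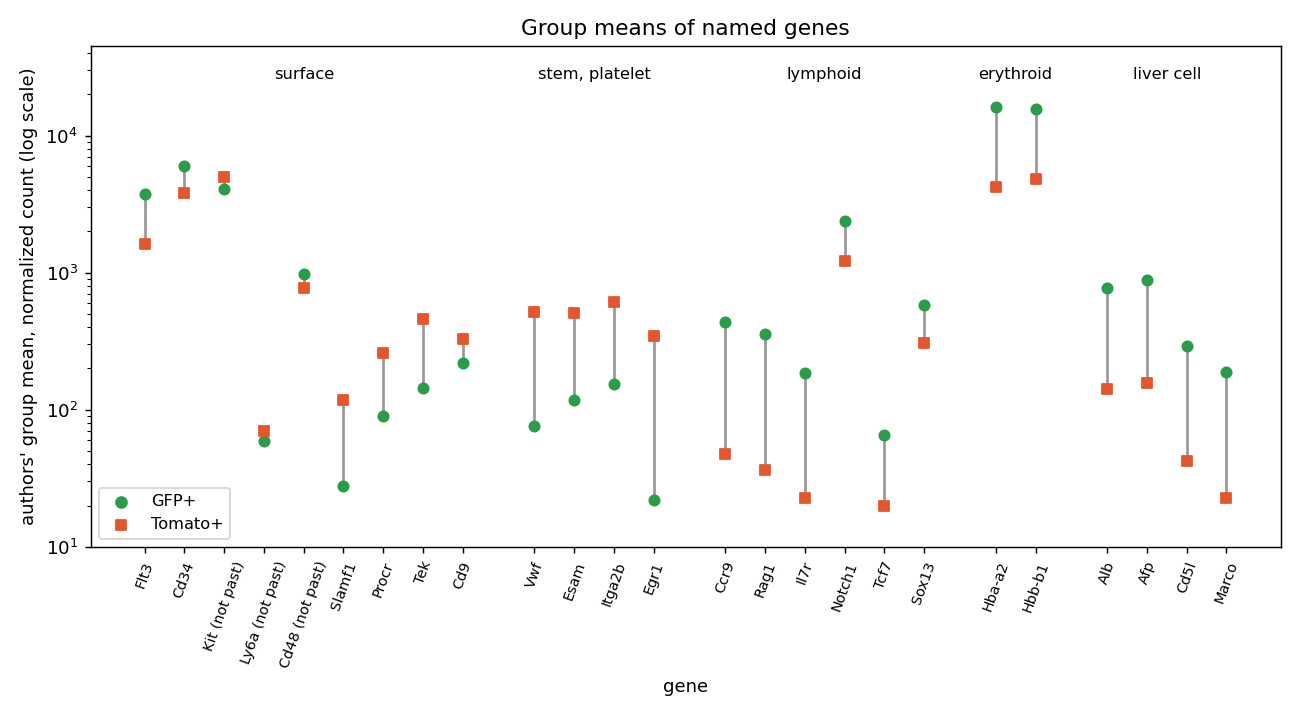
The authors' group means of named genes in normalized counts on a log scale, with green circles for GFP+, orange squares for Tomato+ and grey lines joining both means of a gene; no error bars are drawn because the table gives no spread. Flt3, Ccr9, Rag1, Hba-a2 and Alb lie higher in GFP+, Slamf1, Vwf and Egr1 lower, and the genes marked as not past the authors' adjusted p of 0.05 are Kit, Ly6a and Cd48.

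Of 27 myeloid genes, 4 rose and 4 fell (5 and 4 adjusted over the list alone), and the median log2 of -0.08 lay within the range of matched random lists. Elane, neutrophil elastase, fell 5.47-fold, and Ngp, a granule protein of neutrophils, rose 3.05-fold in the authors' deposited table. None of 8 mast cell, basophil and eosinophil genes passed, also when adjusted over the list alone, with 3 at an unadjusted p under 0.05. Hdc and Cpa3 had log2 values of -1.08 and -0.59 in the authors' deposited table. Of 11 dendritic cell and MHC class II genes only Flt3 rose (3 rose adjusted over the list alone), with a median of 0.55, and Itgax had a log2 of 2.01 and adjusted p = 0.0678 in the authors' deposited table.

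Of 24 immediate early and stress genes 4 fell and 1 rose (6 and 3 adjusted over the list alone), with a median log2 of -0.42 against -0.14 to 0.15 in matched random lists. Fos, Egr1 and Jun, transcription factor genes induced within minutes of stimulation, fell 47.5-fold, 15.5-fold and 5.05-fold in the authors' deposited table. The Fos mean in GFP+ was only 2.47 normalized counts in the authors' deposited table, against 117 in Tomato+. Among quiescence genes and kinase inhibitors 2 of 17 rose and 1 fell (3 and 2 adjusted over the list alone), with a median of 0.09. Ccnd1, which encodes cyclin D1, rose 1.85-fold in the authors' deposited table. Of 37 proliferation genes 5 rose and 0 fell (10 and 0 adjusted over the list alone), and 35 had a log2 above 0, with a median of 0.29 against 0.05 to 0.23 in matched random lists. Ube2c and Rrm2, both of dividing cells, rose 1.55-fold and 1.30-fold in the authors' deposited table.

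Ribosomal protein genes rose in 35 of 39 cases and fell in 0 (39 and 0 adjusted over the list alone), with a median log2 of 0.40 against 0.14 to 0.30 in matched random lists. The 163 rows with a mean of at least 5000, some of them ribosomal protein genes, had a similar median of 0.38. The 20 bins of the matching do not set such rows apart. Rps2 and Rplp1 rose 1.53-fold and 1.41-fold in the authors' deposited table. Of 30 genes of oxidative phosphorylation 7 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.30, and Cycs and Cox4i1 rose 1.44-fold and 1.36-fold in the authors' deposited table. Of 21 genes of glycolysis and hypoxia 5 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.18 that lay within the -0.01 to 0.25 of matched random lists, and Gapdh and Slc2a1 rose 1.64-fold and 1.41-fold in the authors' deposited table. Scaling both groups to the same total, an alternative chosen after seeing the data, lowers every log2 value by 0.16. It leaves medians of 0.24 for ribosomal proteins, 0.14 for oxidative phosphorylation, 0.14 for proliferation, 0.02 for glycolysis and 0.20 for erythroid genes. The ranges of matched random lists move down by the same amount, so no list changes its place relative to its range.

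In the fetal stem cell programme 4 of 17 genes rose and 5 fell (6 and 5 adjusted over the list alone). Its median log2 was -0.21, but 0.17 among members with a mean of at least 50. Grb10, an imprinted growth regulator, fell 3.26-fold and Mest, also imprinted, 5.82-fold in the authors' deposited table, while Afp of the hepatoblast group was among the rises. Of 20 Notch and Wnt genes 3 rose and 1 fell (3 and 2 adjusted over the list alone), with a median of -0.01. Of 25 adhesion and homing genes 4 rose and 4 fell (5 and 7 adjusted over the list alone), with a median of 0.04. Of 19 p53 targets and apoptosis genes only Bcl2l1 rose, 1.34-fold in the authors' deposited table (1 adjusted over the list alone), and the median was 0.07. Pmaip1 of that list had a log2 of 1.11 and adjusted p = 0.577 in the authors' deposited table.

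None of 30 interferon response genes passed, also when adjusted over the list alone, with 4 at an unadjusted p under 0.05 and a median log2 of -0.01. Rtp4 and Ifitm1 had log2 values of 0.65 and -0.48 in the authors' deposited table. None of 17 replication-dependent histone genes passed either, also when adjusted over the list alone, with 6 at an unadjusted p under 0.05. All 17 had a log2 above 0, and the median of 1.02 was 0.33 among members with a mean of at least 50. Hist2h3c1 and Hist1h3b had adjusted p = 0.0937 and 0.0995 in the authors' deposited table. Of 6 sex-linked genes Xist, the RNA of the inactive X chromosome, rose 4.67-fold in the authors' deposited table (1 adjusted over the list alone), and Tsix had a log2 of 1.64 and adjusted p = 0.442. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty, chosen after their values were seen, had log2 values of 0.02, -0.20, -0.16 and -0.09 and did not pass in the authors' deposited table. Median and mean log2 differed in sign for the quiescence, p53, Notch and Wnt, and sex-linked lists.

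Further large differences were seen in genes that are in none of the fixed lists, which does not show that they are separate from the groups above. Gfra1, a receptor of the GDNF family, Stc1, a secreted glycoprotein, H4, Cdh17, a cadherin, and Fcna, a ficolin, rose by 3.59, 3.45, 3.11, 2.82 and 2.75 on the log2 scale in the authors' deposited table. Which gene the symbol H4 stands for was not established. Ptrf, a coat protein of caveolae, Pdzk1ip1, Dach1 and Ehd3 fell 6.92-fold, 5.49-fold, 5.30-fold and 4.96-fold in the authors' deposited table. The p-values behind these calls are the authors' own, and the spread between libraries could not be examined.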

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

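No paired analysis was possible because the table used here holds group means and no value per library. For the same reason the planned replicate block, other size factors, removal of the filter on counts per library, pseudocounts, estimated correlation between genes and leaving out of single libraries were not run, nor were other splits of the libraries. The depth per library is unknown, which limits what can be said of genes with low means. The alternatives that rescale to equal totals, leave out hepatoblast, macrophage and erythroid genes or leave out rows with a mean of at least 5000 were chosen after seeing the data. Against 1069 calls (693 higher, 376 lower), an adjusted p under 0.01 gave 699 (445 higher), a minimum change of 1 on the log2 scale 492 (275 and 217), and a Bonferroni adjustment 308 (190 and 118), each by a stricter criterion. The higher genes made up 64.8% of the calls, 55.9% with that minimum change, 61.7% with Bonferroni and 60.7% without rows of a mean of at least 5000. Counts ranged from 956 to 1374 under the other alternatives. Without hepatoblast, macrophage and erythroid genes 1023 calls were left. Of the 28 list medians, 19 lay outside the random range, and 16 to 21 under the alternatives. The median of the fetal stem cell programme turned from -0.21 to 0.17 among members with a mean of at least 50. The cause was not tested. No other list median outside its random range changed sign. Among the genes in the text past the threshold 3 with small changes, chosen after their values were seen, turned, since the shift exceeds their change: Cpox from 0.02 to -0.0065 with centring and -0.13 with rescaling, and with rescaling Rhag from 0.15 to -0.0085 and Ppp1r15a from 0.079 to -0.078.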

Other observations

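All genes of this paragraph were chosen after their values were seen. Igf2, a fetal growth factor, and Meg3, an imprinted noncoding RNA, fell 2.37-fold and 3.77-fold in the authors' deposited table. Apoe, which encodes an apolipoprotein, fell from a mean of 2272 in Tomato+ to 832 in GFP+ in the authors' deposited table. Myc rose by 0.59 and Satb1, a chromatin organiser of lymphoid cells, by 1.02 on the log2 scale in the authors' deposited table. Hmga2, of the fetal programme, rose 1.29-fold, and Lin28b had a log2 of 0.23 and adjusted p = 0.61 in the authors' deposited table.

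The authors' ratios and p-values did not always go together. Among 959 genes with a mean of at least 100 and a p under 0.01, 5 had a p-value smaller than counting error alone would give for their ratio at their mean. They were Blvrb, Ppp1r15a, Cpox, Rhag and Mt2, chosen after their values were seen. Cpox, of heme synthesis, had means of 1261 and 1240 with adjusted p = 0.0139 in the authors' deposited table, and would have needed 16.3 times as many reads as its mean implies. What sets such p-values was not tested.

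The tests below of further erythroblast genes, of Gata1, Klf1 and Epor, of heat shock genes, of T cell genes, of stromal against hepatocyte quartiles and of the implied spread were chosen after the results they bear on, or part of them, had been seen. For the implied spread, the medians of 94.4 and 78.9 given below passed the bound of 75 set at first. The condition that simulated genes pass it under both ways of making p-values was added after those medians had been seen, and it was not met.

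Most hepatoblast, macrophage and erythroid genes were higher in GFP+. More of every liver cell type in that sort would raise stromal genes too, but the sets moved apart. The 17 further stromal genes had an upper quartile of 0.24 and further hepatocyte genes a lower quartile of 0.71 on the log2 scale. This does not decide on stromal cells, since lower expression in the sorted cells could hide their input. Fstl1 and Fn1, chosen after their values were seen, passed as lower from Tomato+ means of 525 and 351. Of the 17 genes, 4 passed as lower and 1 as higher. The stromal median of -0.34 by itself lay within the -0.44 to 0.19 of matched random lists, with 5 genes above 0, and the endothelial median was -0.91, although stem cells share part of these genes. The 3 cell types themselves, or their free RNA, may have entered the GFP+ sort, although a sort of lineage-negative cells positive for Kit, Sca1 and CD150 is meant to leave them out: further hepatocyte genes had a median of 1.99 (15 of 20 above 0, 9 past the threshold as higher), further macrophage genes 0.79 (22 of 26, 4) and further erythroblast genes 0.31 (25 of 31, 17), each with 0 lower and at percentile 100 of matched random lists, but each missed the share or size set for it. The 17 called erythroblast genes include Cpox, chosen after its values were seen. Its log2 was only 0.02, with a p-value smaller than counting error alone would give. Apoe, an apolipoprotein of liver cells and macrophages that is in none of these lists, fell from 2272 in Tomato+ to 832 in GFP+ in the authors' deposited table. It was chosen after its values were seen. Its Tomato+ mean was far above those of Alb (142) and Cd5l (42.4), so much of it may come from the sorted cells. Apoe therefore does not decide on these cell types. A turn of GFP+ cells towards the erythroid lineage would raise Gata1, Klf1 and Epor, whose median was -0.89 with only Gata1 past the threshold, as lower. The loss of megakaryocyte genes could hide a rise in Gata1, which is in the megakaryocyte list. Klf1 and Epor are not in that list and had log2 values of -0.46 and -0.89 without passing. Whether the same loss lowers them too was not tested. These explanations, and a difference between the fractions themselves, cannot be told apart without values per library.

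Fos, Fosb, Egr1 and Jun were lower in GFP+, with Fosb (chosen after its values were seen) at 0.51 and 34.1 normalized counts in the authors' deposited table. Heat shock from handling of the Tomato+ sort would lower heat shock genes in GFP+. The 7 genes read had a median log2 of 0.15, with 5 above 0, within the -0.21 to 0.35 of matched random lists. That median falls below the bound of 0 set for it when every log2 value is lowered by 0.16. It does so only with Ddit3 counted among the 7. Ddit3, chosen after its values were seen, had a log2 of -0.48 and is a gene of endoplasmic reticulum stress rather than heat shock. All 7 are also in the fixed immediate early and stress list. Only Hspa8, chosen after its values were seen, passed, as higher, with a mean of at least 5000, where genes leaned towards GFP+. These genes therefore do not decide on heat shock. Induction of immediate early genes at large stays open, since 27 further genes of that kind had a median of -0.23, at percentile 1.96 of matched random lists, with 0 past the threshold as lower and 1, Dusp6 (chosen after its values were seen), past it as higher. Induction that differed between libraries stays open too: the spread implied by the authors' p-values had a median percentile of 94.4 among genes of like mean and change, over the 5 of 24 list members with a change of at least 1 on the log2 scale and an unadjusted p under 0.5. That value does not decide. Simulated genes with all their extra expression in 1 GFP+ library came at 100 where p-values used each gene's own spread. They came at 10.8 where p-values used a shared spread, and which of these the authors used is not given in the sources used here. The simulated genes rose in GFP+, whereas Fos, Fosb, Egr1 and Jun fell, so the simulation also differed from them. A difference in resting state between the fractions was not tested.

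B-lineage genes were higher in GFP+. B-lineage cells as the only source of the lymphoid difference stay open: the 11 measured T and innate-like genes, none of them in the B list, had a median log2 of 0.92 at percentile 99.98 of matched random lists, but 6 lay above 0 and 5 below. Some B-lineage cells in the sort, which a lineage gate would be meant to remove, cannot be told apart from priming of the GFP+ cells: 17 further B-lineage genes, some also made by stem cells, had a median of 0.62 at percentile 100 of matched random lists, with 17 above 0 and 7 past the threshold as higher, but short of the size set for it. Whether expression was concentrated in a few libraries stays open for the same reason, with a median percentile of the implied spread of 78.9 over 14 genes of the B list.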
